A study of Mus musculus with 4 samples.

How the data were processed

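RNA was extracted with TRIzol from 4 samples of brain tissue, and libraries were made with a dual-mode mRNA kit for Illumina sequencing. The authors give GRCm38 as the assembly, per the submitters' processing notes. The aligner, the quantification program, the annotation and the use of strand are not given in the sources used here. The deposited values are read as FPKM from their behaviour, because neither the labels nor the file headers name the unit. They are not whole numbers, their totals differ between libraries, and in genes with a single transcript the product of value and length gathers at multiples of a common step. Between 26.7% and 28.1% of the low values under 0.3 FPKM lay within 0.05 of a whole step, so reads could not be recovered and no counts were inferred. The step gives the fragment numbers in the report, and counting intervals were not computed.

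All samples belong to 1 group, naive mice. The column of the sample titled as the third replicate is headed with the letter C in place of a number, and it was taken as replicate 3 from its title. No label beyond the numbering states that the replicates are separate animals, so the p-values measure only the spread between these samples. No per-sample columns were left unused. The tables hold 25044 entries, of which 22036 carry Ensembl identifiers and 3008 are loci without one. Symbols and coordinates came from GENCODE M21, which matched 22022 identifiers.

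The lists of genes, the tests and most alternatives were chosen before the data were examined. The design allowed for counts or for normalized values, and the branch for normalized values was used. Genes with a mean of 0.1 FPKM or more were kept, 17630 in all, and values were taken as log2(FPKM + 0.1), a scale that understates differences of low genes. Each gene was compared with a reference gene within libraries by limma 3.58.1 in R 4.3.3, fitting only an intercept to the differences, two-sided, with Benjamini-Hochberg adjustment over 17629 genes and a threshold of 0.05.

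The treatment of limma's prior was changed after values had been seen. The planned empirical Bayes fit was run first, and because every difference shares the deviation of the reference gene, its prior degrees of freedom became infinite for Adcyap1 and Slc17a6 and 4.23 for Adcyap1r1. Replacements with a prior from randomly paired genes, and with the prior degrees of freedom limited to the 3.78 of a fit of the genes' own levels, were then tried. The limited prior was kept because on data simulated with the observed SD of the reference gene its share of unadjusted p under 0.05 among unchanged genes was nearest the nominal 5% for Adcyap1, at 4.95% against 6.75% for the planned fit and 17% for random pairs. For Slc17a6 the shares were 4.26%, 5.82% and 8.8%, so there the planned fit lay about as near. For Adcyap1r1 they were 3.49%, 4.24% and 3.13%, so there the planned fit lay nearer. With the SD of the reference drawn at random instead, the shares of the limited prior, the planned fit and random pairs were 4.57%, 5.38% and 3.97% for Adcyap1, 3.66%, 4.32% and 3.17% for Adcyap1r1 and 5.38%, 6.18% and 4.89% for Slc17a6, so the limited prior was nearest for none of them. The simulations drew gene variances with a spread set close to that of the real data, which the limited prior also assumes. Its shares near 5% were therefore partly built in and are no independent reason for the choice. The planned fit and the random pairs are given as alternatives. With the observed SD the limited prior recovered 33.2% of genes simulated 0.5 log2 units above Adcyap1, 82% of those at 1 and 100% of those at 2, and 98.9% and 91.1% of those at 0.5 above Adcyap1r1 and Slc17a6. With a drawn SD it recovered 98% of those at 0.5 above Adcyap1.

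The level of each of 39 lists was the median percentile of its members per library. It was tested by a two-sided permutation against 10000 random lists of equal size, with Benjamini-Hochberg adjustment over the lists. Among random lists tested in the same way, 5.5% had an unadjusted p under 0.05. The median difference of a list between a library and the mean of the others was set beside 10000 random lists matched in 20 bins of level. Variance between libraries was tested with limma's trended, robust prior (4.28 prior degrees of freedom). Genes, which are not independent replicates, were the units of the correlations between libraries. Single libraries far from the rest were found by Dixon's test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

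The genes named were fixed by a rule. It takes Adcyap1, Vip and their receptors, the 8 most abundant precursors and receptors, all transmitter genes, the 3 most abundant members of every other list, the 10 most abundant genes not encoded by mitochondria, and genes passing the variance test. Other names are said to be chosen after their values were seen. Some genes that the rule takes are not reported here, though counts over lists include them. No entry was found for 10 listed genes, namely Cyr61, Malat1, Rmrp, Rn45s, Rn7sk, Rpph1, Tsix, Xist, mt-Rnr1 and mt-Rnr2. Levels are uncertain where exons overlap another gene, as for Pmch, Gnas, mt-Atp6, Pcsk1n and Aldoa, and where paralogs are nearly identical, as for Hba-a1 and Hba-a2. Dbh was below the filter, with a mean of 0.0169 FPKM. Alternatives changed the value added, the filter, the length correction, the background, the summary, the scaling, the prior and the libraries included. The length correction was undone only roughly, by multiplying by the longest GENCODE M21 transcript, because the lengths behind the deposited values are not given.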

Results

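Transcript levels were measured by RNA sequencing of brain tissue taken from the parasubthalamic nucleus of naive C57BL/6 mice, an inbred laboratory strain. The parasubthalamic nucleus is a small cell group at the border of the posterior lateral hypothalamus and the subthalamic nucleus. The 4 libraries, called replicates 1 to 4, formed 1 group, and no stressed animals were sequenced, so the comparisons are between genes within the libraries and between the libraries themselves. The values were read as FPKM, fragments scaled to transcript length and library depth, although neither labels nor headers name the unit. Totals per library were 442836 FPKM in replicate 1, 428612 in replicate 2, 434114 in replicate 3 and 430075 in replicate 4. Spacing between low values implied 20900000, 20400000, 19300000 and 19800000 fragments in the same order. At 1 FPKM or more, 12415 entries were found in all 4 libraries, of which 392 were loci without an Ensembl identifier. Transcripts of the mitochondrial genome took 20.7% ± 1.45 (SD, n = 4) of the total. Across 17630 genes, which are not independent replicates, Pearson correlations of log2 levels lay between 0.972 and 0.981 for the 6 pairs of libraries.

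The series asks which genes are abundant in this tissue and names the peptide PACAP in its title, so each neuropeptide precursor was set against the PACAP precursor gene. Adcyap1, which encodes the pituitary adenylate cyclase-activating polypeptide PACAP, lay at 39.8 ± 13.8 FPKM (SD, n = 4) and ranked 8 in its list by mean level. Pmch, the precursor of melanin-concentrating hormone, was 5.51-fold higher than Adcyap1, and Cartpt, the precursor of CART peptides, was 3.72-fold higher. Sst, which encodes somatostatin, was 2.92-fold higher, and Cck, the cholecystokinin gene, was 2.21-fold higher. Tac1, the substance P precursor, and Penk, the enkephalin precursor, were 1.92-fold and 1.69-fold higher. Vip, whose peptide shares receptors with PACAP, lay at 2.31 ± 0.917 FPKM, 16.8-fold below Adcyap1.

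Of the 46 precursors tested, 6 were higher than Adcyap1 (ENSMUSG00000024256, GRCm38 chromosome 17, 93199017 to 93206537), 36 were lower and 4 did not pass. The counts adjusted over the list alone were also 6 and 36. By mean level Adcyap1 stood at percentile 89.7 of all genes tested. Most genes of any kind therefore lie below it, and the count of lower precursors is not by itself particular to them. The 6 higher genes were above Adcyap1 in 4 of 4 libraries, though Cck was at 58.1 FPKM and level with it to that precision in replicate 1. In limma, Pmch had a log2 difference of 2.46 (SE 0.40, adjusted p = 0.000698) and Cartpt of 1.89 (SE 0.37, adjusted p = 0.00195). Sst followed at 1.55 (SE 0.32, adjusted p = 0.00280), Cck at 1.14 (SE 0.40, adjusted p = 0.0295), Tac1 at 0.94 (SE 0.24, adjusted p = 0.00687) and Penk at 0.75 (SE 0.24, adjusted p = 0.0193). Vip was at -4.07 (SE 0.35, adjusted p = 2.10e-05) and below Adcyap1 in all 4 libraries. Hcrt, the orexin precursor, did not pass at -0.80 (SE 0.77, adjusted p = 0.350): it was above Adcyap1 in 2 of 4 libraries, at 119 and 91.4 FPKM in replicates 1 and 4, and at 7.72 and 2.60 FPKM in replicates 2 and 3. Hcrt did pass as lower without length correction, at -3.32, and with the planned limma prior, at -0.80. Npy, Ucn and Avp, named after their values were seen, also did not pass, at -0.76 (adjusted p = 0.0715, higher in 1 of 4), -1.05 (adjusted p = 0.0700, higher in 0 of 4) and -1.77 (adjusted p = 0.0962, higher in 1 of 4). With the planned limma prior 40 precursors passed as lower and 6 as higher, so Npy, Ucn and Avp passed as lower there too. The number of higher precursors was 3 without replicate 2, 4 without replicate 3 and 3 without replicate 4, with Cck (1.15, 0.70 and 1.19) and Penk (0.67, 0.70 and 0.77) lost in each case and Tac1 lost without replicate 2 (0.84) or 4 (0.91). Values were also multiplied by the length of the longest annotated transcript, which ranks genes roughly by fragments. On these values 0 precursors passed as higher, and the differences of Sst, Cck and Penk changed sign.

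**Figure D1:**
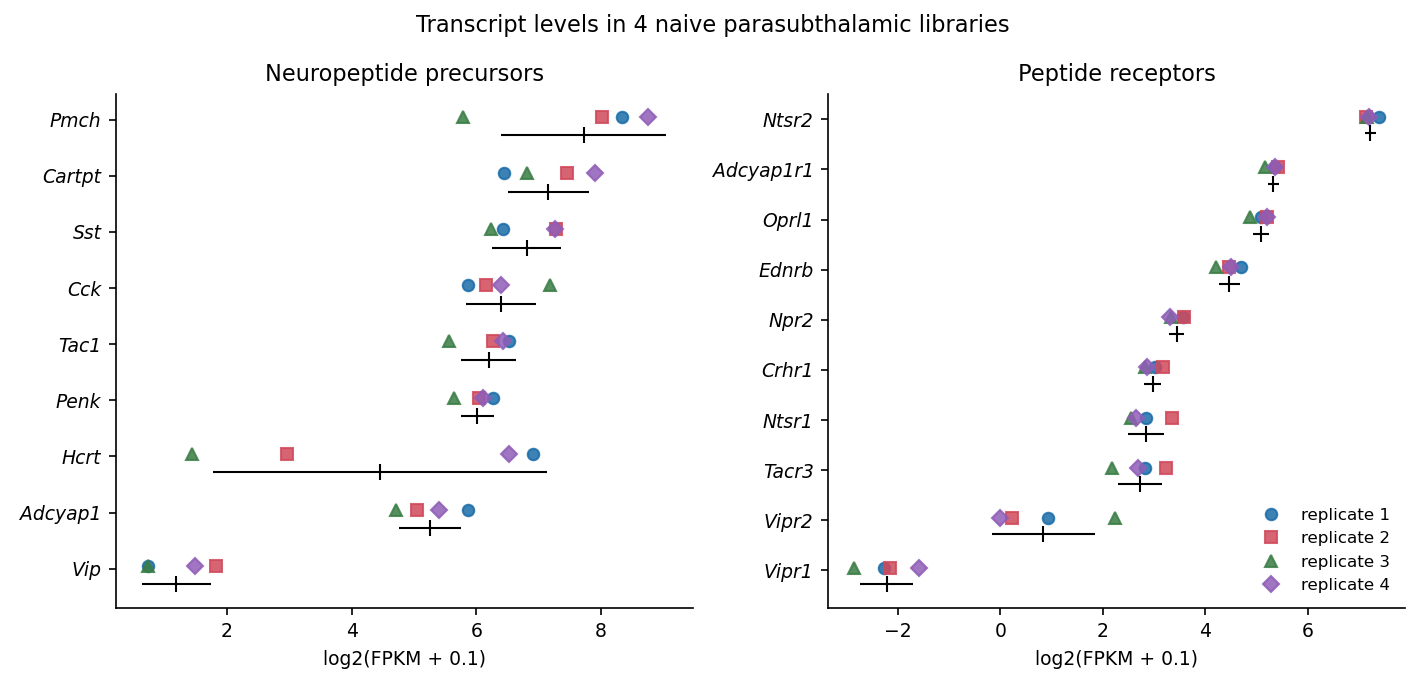
Levels of neuropeptide precursor genes (left) and peptide receptor genes (right) as log2(FPKM + 0.1); each marker is 1 of the 4 libraries, and the black tick and line are the mean ± SD on that scale. Adcyap1 has a mean of 39.8 FPKM and Adcyap1r1 a mean of 40.0 FPKM, with Vip, Vipr2 and Vipr1 lower in all 4 libraries.

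The peptide receptors were set against Adcyap1r1, which encodes PAC1R, the receptor selective for PACAP. Adcyap1r1 (ENSMUSG00000029778, GRCm38 chromosome 6, 55451978 to 55501451) lay at 40.0 ± 2.98 FPKM (SD, n = 4) and ranked 2 in its list. Ntsr2, a neurotensin receptor found mainly in astrocytes, was 3.71-fold higher at 149 ± 11.6 FPKM. Oprl1, the nociceptin receptor, was 1.18-fold lower at 34.0 ± 3.59 FPKM, and Ednrb, an endothelin receptor, was 1.82-fold lower at 22.1 ± 3.13 FPKM. The receptors that bind PACAP and VIP alike were far lower: Vipr2 at 2.09 ± 1.72 FPKM by 22.4-fold and Vipr1 at 0.126 ± 0.0798 FPKM by 186-fold. Crhr1, a receptor of corticotropin-releasing hormone, was 5.12-fold lower at 7.77 ± 0.910 FPKM.

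Of 60 receptors tested in limma, 1 was higher and 59 were lower, and the counts adjusted over the list alone were again 1 and 59. By mean level Adcyap1r1 stood at percentile 89.8 of all genes tested. Most genes of any kind therefore lie below it, and the count of lower receptors is not by itself particular to them. Ntsr2 was higher in 4 of 4 libraries with a log2 difference of 1.89 (SE 0.07, adjusted p = 5.80e-08). Oprl1 was lower in 4 of 4 at -0.24 (SE 0.05, adjusted p = 0.00349), Vipr2 in 4 of 4 at -4.48 (SE 0.38, adjusted p = 1.08e-05) and Vipr1 in 4 of 4 at -7.54 (SE 0.29, adjusted p = 1.01e-07). Vipr2 was at 4.61 FPKM in replicate 3 and between 0.891 and 1.79 FPKM in the others. The Vipr1 difference depends on the value added before taking logarithms and was -5.19 with 1 and -8.41 with 0.01 in place of 0.1, and that of Vipr2 was -3.87 with 1. Without length correction the directions were the same but the sizes were not, with Ntsr2 at 0.75, Oprl1 at -1.21, Crhr1 at -3.67, Vipr2 at -5.40 and Vipr1 at -8.59.

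The design text concerns glutamatergic neurons, so transmitter genes were set against Slc17a6, which encodes the vesicular glutamate transporter VGLUT2. Slc17a6 (ENSMUSG00000030500, GRCm38 chromosome 7, 51622006 to 51671119) lay at 80.0 ± 10.52 FPKM (SD, n = 4). The other vesicular glutamate transporters were lower, Slc17a7 by 13.0-fold at 12.2 ± 13.5 FPKM and Slc17a8 by 114-fold at 0.832 ± 0.907 FPKM. Among genes of inhibitory neurons, Gad1, an enzyme of GABA synthesis, was 1.47-fold higher at 119 ± 20.5 FPKM. Slc32a1, the vesicular GABA transporter, and Gad2 were 1.43-fold and 1.46-fold lower. Th, the rate-limiting enzyme of dopamine synthesis, was 1.63-fold higher at 137 ± 57.4 FPKM. These are levels of bulk tissue and do not show which cells held Th. Markers of midbrain dopamine neurons stood high as a list in all 4 libraries, as given below.

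Of 17 transmitter genes tested in limma, 3 were higher than Slc17a6, 12 were lower and 2 did not pass, with the same counts adjusted over the list alone. By mean level Slc17a6 stood at percentile 95.4 of all genes tested, so most genes of any kind lie below it. Th had a log2 difference of 0.71 (SE 0.25, adjusted p = 0.0294) and Gad1 of 0.56 (SE 0.17, adjusted p = 0.0163), each higher in 4 of 4 libraries. Slc32a1 was at -0.52 (SE 0.16, adjusted p = 0.0146) and Gad2 at -0.55 (SE 0.15, adjusted p = 0.00955), each lower in 4 of 4. Slc17a7 was at -3.70 (SE 0.76, adjusted p = 0.00205) and lower in 4 of 4, and ranged from 0.830 FPKM in replicate 1 to 30.6 in replicate 3. Its difference was -2.73 without replicate 1 and -4.46 without replicate 3, and that of Slc17a8, -6.83, was -7.49 without replicate 2 and -5.57 with 1 in place of 0.1 added before taking logarithms. The dopamine transporter Slc6a3 did not pass at 0.47 (adjusted p = 0.128, higher in 4 of 4), nor did the decarboxylase Ddc at 0.34 (adjusted p = 0.231, higher in 2 of 4). Th, Slc6a3 and Ddc were each highest in replicate 2, at 223, 196 and 174 FPKM, and Slc18a2, the vesicular monoamine transporter, at 78.9 FPKM was above Slc17a6 in that library while passing as lower at -0.82 (SE 0.26, adjusted p = 0.0186). Gad1 did not pass without replicate 3 (0.52) or 4 (0.59), Slc32a1 without replicate 1 (-0.38), 3 (-0.52) or 4 (-0.50), and Slc18a2 without replicate 1 (-0.73), 3 (-0.67) or 4 (-0.69), while Ddc turned to -0.01 and Th was at 0.35, still passing, without replicate 2. On values multiplied back by transcript length 1 gene passed as higher, Th changed sign, Ddc passed as lower at -0.69, Gad1 no longer passed at 0.36 and Gad2 no longer passed at -0.08, and with the limma prior left without a limit on its degrees of freedom 5 genes passed as higher.

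Marker lists of cell types and regions described what the tissue pieces held. A list's level is the median percentile of its genes among the 17630 tested. Neurons stood at 98.3 ± 0.169 (SD, n = 4), with the synaptic gene Snap25 at 1133 FPKM, and oligodendrocytes at 98.5 ± 0.349, with the myelin gene Mbp at 4560 FPKM. Astrocytes stood at 95.1 ± 0.610, with the glycolytic enzyme gene Aldoc at 541 FPKM, and the granins and peptide-processing enzymes at 96.6 ± 0.275, with the carboxypeptidase Cpe at 1278 FPKM. The list of PACAP receptor signalling, which holds G protein and protein kinase A subunits such as Prkar1b at 309 FPKM, stood at 76.6 ± 2.11.

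The permutation p against 10000 random lists was 0.0002, the smallest that they can give, for neurons, oligodendrocytes, astrocytes, peptide processing, PACAP receptor signalling and the mitochondrial genes at 99.97 (adjusted p = 0.0013 over 39 lists). GABAergic and glycinergic genes stood at 93.0 ± 1.08 (permutation, adjusted p = 0.0226), midbrain dopamine markers at 84.7 ± 3.77 (permutation, adjusted p = 0.0225) and parasubthalamic markers at 82.2 ± 3.89 (permutation, adjusted p = 0.0225). Each of these 9 lists was above random in 4 of 4 libraries. Peptide receptors stood below random at 30.2 ± 1.28 in 4 of 4 libraries (permutation, adjusted p = 0.00557), but at 48.4, without passing, when all genes served as the background, an alternative chosen after seeing the data. The parasubthalamic list holds genes that other lists also hold, such as Slc17a6, Cck and the calretinin gene Calb2 at 178 ± 40.8 FPKM. With genes of a mean of 1 FPKM or more as the background, 5 lists passed as above, and parasubthalamic, dopamine, GABAergic and PACAP signalling genes did not. The parasubthalamic list also did not pass without length correction, at 67.5, nor did the GABAergic list by mean log2 level, at 4.91.

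Among the other region lists, no level passed with the length correction; without it, medial hypothalamus at 18.6 and cortex and hippocampus at 18.1 passed as below. Lateral hypothalamus markers stood at 70.3 ± 14.4, thalamus at 58.2 ± 18.1, mammillary nuclei at 49.4 ± 2.78, zona incerta at 48.0 ± 4.51 and the subthalamic nucleus at 46.5 ± 2.83. Medial hypothalamus stood at 41.8 ± 13.7, striatum at 41.5 ± 4.42, and cortex and hippocampus at 25.5 ± 4.90. The large SD of the lateral hypothalamus, medial hypothalamus and thalamus lists came with libraries that stood apart. In replicate 2 the median gene of the medial hypothalamus list was 2.42 log2 units above the mean of the other libraries, with Avp, the vasopressin gene, at 90.5 FPKM and Pomc at 30.1 FPKM. The pituitary list, which also holds Pomc, was higher there by 2.13 with 4 of the 4 members tested higher, and the pituitary hormone subunit gene Cga was at 12.1 FPKM. That list has 8 genes, of which 4 were below the filter. In the same library all 10 midbrain dopamine markers were higher, by a median of 1.02. In replicate 3 the thalamus list was higher by 2.14, with the protein kinase gene Prkcd at 172 FPKM against 3.72 to 13.4 elsewhere, while the medial hypothalamus list was at -1.85 and the lateral hypothalamus list at -0.88. In replicate 4 the lateral hypothalamus list was higher by 0.83, and in replicate 1 the oligodendrocyte list was at -0.38, the mural cell and fibroblast list at 0.56 and the heat shock list at 0.26. The parasubthalamic list was at 0.41 in replicate 1, -0.24 in replicate 2, -0.45 in replicate 3 and 0.21 in replicate 4. All of these medians lay outside the range of matched random lists, which describes these libraries and carries no p-value. Many other lists also lay outside it, such as the mitochondrial genes and the neuropeptide precursors in all 4 libraries. The random lists were matched on level alone, so lying outside does not by itself set a library apart.

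**Figure D2:**
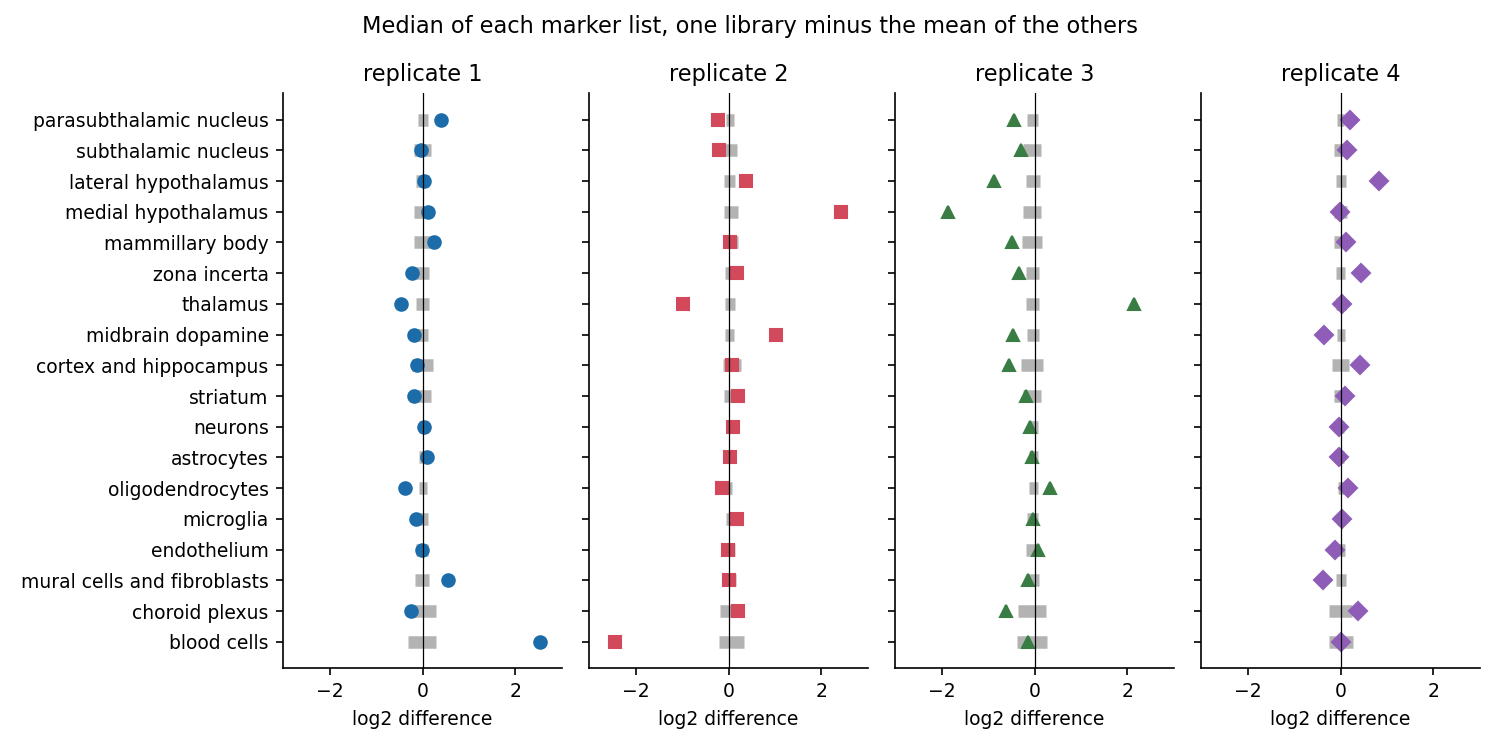
Median log2 difference of each region or cell type list between 1 library and the mean of the other 3, with 1 panel per library; markers are the lists and grey bars span the central range of 10000 random lists matched on level. The medial hypothalamus list is at 2.42 in replicate 2 and the thalamus list at 2.14 in replicate 3.

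Genes were also compared for their spread between libraries. The genes with the highest ratios of variance to that of genes of like level were Hcrt and Prkcd, followed by Avp, and none of these passed. The limma variance test called 0 of 17630 genes, with 1031 at an unadjusted p under 0.05. Hcrt and Prkcd both had an adjusted p of 0.0760 and Avp of 0.0772, and these genes were named after their values were seen. Without replicate 3 the test called 4 genes, Oxt, Avp, Hcrt and Ttr, and without replicate 4 it called 8, among them Prkcd, Oxt, Avp and Hcrt. On simulated data the test recovered 0% of genes shifted by 4 log2 units in a single library, so its count of 0 does not show that genes varied alike.

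**Figure D3:**
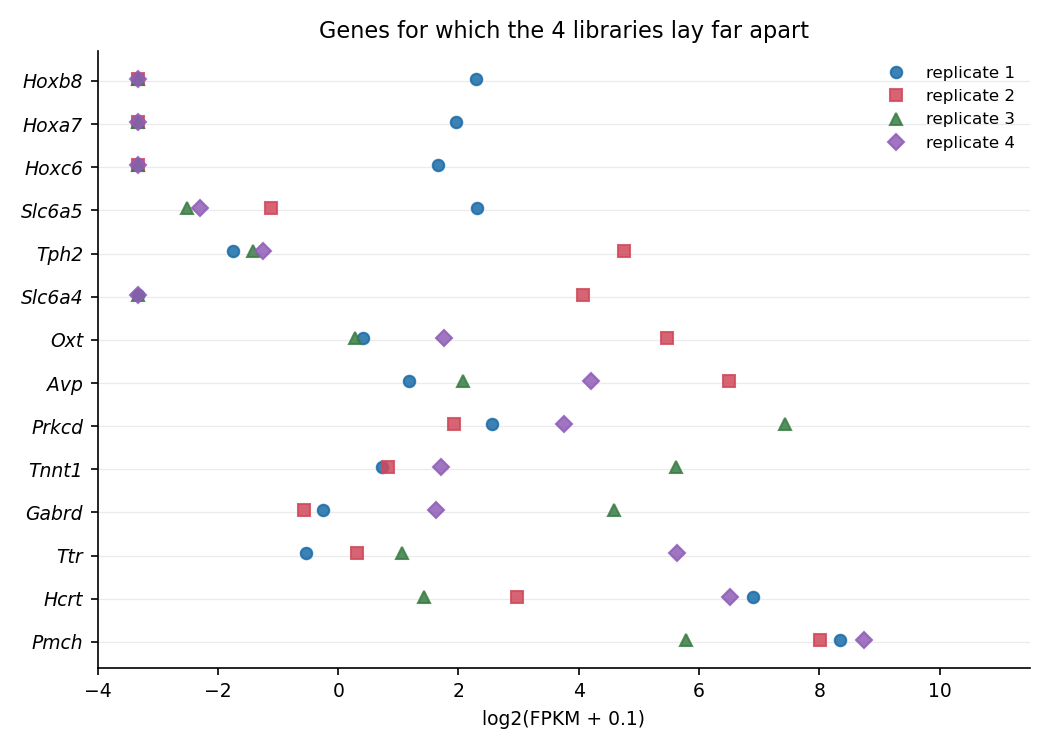
Levels, as log2(FPKM + 0.1), of genes chosen after their values were seen because the libraries lay far apart; each marker is 1 of the 4 libraries. Hoxb8 is at 4.81 FPKM in replicate 1 and listed at 0 in the others, and Tph2 is at 26.7 FPKM in replicate 2.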

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

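The tests on the number of Hox clusters, on Tph2, on the first thalamus list and on dilution were chosen after the result was seen, and the other tests were added once the patterns were known but before their own values were. A single library lay far from the other 3 by Dixon's test for 20 of the 173 values tested, against about 5% by chance, with 7 in replicate 1, 8 in replicate 2, 4 in replicate 3 and 1 in replicate 4. The 5% assumes normally distributed values, which FPKM need not be. The values tested are also not independent of each other, so the 5% is only a rough guide.

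In replicate 1, 14 of 39 Hox genes, which set position along the body axis caudal to the midbrain, were at 0.5 FPKM or more, and 13 of these were listed at 0 in the other libraries. The highest were Hoxb8 at 4.81, Hoxa7 at 3.80 and Hoxc6 at 3.06 FPKM, and Slc6a5, the glycine transporter of hindbrain and spinal neurons, was at 4.83 FPKM against 0.0746 to 0.361. The genes came from 4 Hox clusters, which argues against reads mis-assigned at a single locus, and 0.23% of 5653 other genes of like level were listed at 0 in the other libraries, which argues against failed estimates there. Spinal cord or caudal hindbrain tissue may have entered the sample: a spinal cord list, with 6 of 12 members tested and 2 of them at a mean of 1 FPKM or more in the other libraries, lay at percentile 99.6 of random lists, its most abundant members being Prph at 12.7 against 8.16 FPKM and Slc5a7 at 3.67 against 1.67. Isl2, another member tested, was at 0.349 against 0.0387 FPKM and passed the filter of 0.1 FPKM only through replicate 1. Its entry favoured a high percentile there. The same list lay at 97.82 in replicate 2, where Prph was at 12.35 and Slc5a7 at 3.51 FPKM. No Hox gene reached 0.5 FPKM in that library, so the list does not separate the libraries cleanly. It lay at 0.23 in replicate 3 and 0.29 in replicate 4. Beyond the tests above, no biological explanation was tested in a design of 1 group.

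In replicate 2, the serotonergic genes Tph2 and Slc6a4 were at 26.7 and 16.7 FPKM, against at most 0.319 FPKM for Tph2 and a listing at 0 for Slc6a4 in the other libraries. Fev, another serotonergic gene chosen after its values were seen, was at 1.62 FPKM there against 0.113 to 0.416 elsewhere. Tph2 was 83.8-fold above the highest other library, which restates the pattern and decides nothing, but 0 of 7372 other genes at 5 to 50 FPKM in replicate 2 were listed at 0 in all of the others (0%), which argues against failed estimates there. Raphe tissue could not be told apart from other sources: a raphe list lay at percentile 95.4 of random lists, short of the bound set beforehand. Of its 8 members, 6 were higher in replicate 2 and 2 were lower. The largest differences either way were those of Gata3 at 0.882 and Nkx6-1 at -0.691 log2 units. At a mean of 1 FPKM or more in the other libraries are 6 of the 8, Maob at 19.4 FPKM among them. Such a baseline could hide a small share of added tissue, but whether it did was not tested. Beyond the tests above, no biological explanation was tested.

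In replicate 3, Prkcd, abundant in thalamic relay neurons, was at 171.9 FPKM against 3.72 to 13.4, while Pmch was lowest there at 54.9 and Hcrt at 2.60 FPKM. The thalamus list lay at percentile 100 of random lists, which restates the pattern, since its own genes showed it. A second list of 7 thalamic genes outside it, all at a mean of 1 FPKM or more in the other libraries, was higher by a median of 0.75, also at percentile 100, with Adarb1 at 58.9 against 25.3 and Shox2 at 15.9 against 2.20 FPKM but Necab1 lower, so thalamic tissue in the sample is a candidate explanation. The median of all genes was -0.0482 log2 units from the other libraries, so the values of this library were not shifted as a whole. FPKM is already scaled to depth, so this median could not reveal an effect of depth. The smaller of the Pmch and Hcrt differences, less the median of the zona incerta list, was -2.25 log2 units. That argues against dilution of an otherwise equal piece of tissue by thalamus. A dissection that also held less lateral hypothalamus stays open, and beyond the tests above no biological explanation was tested.

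Other values of replicate 2 far from the rest were Th at 222.6, Slc6a3 at 195.9, Ddc at 174.3, the dopamine receptor Drd2 at 27.7 against 16.5 to 17.4, the oxytocin gene Oxt at 44.04 against 1.11 to 3.28, and Slc17a8 at 2.19 against 0.254 to 0.453 FPKM. Replicate 3 was highest for the histamine receptor Hrh3 at 31.1 FPKM and the metallothionein Mt1 at 313.7 FPKM, and lowest for Prkar1b at 278.6 FPKM. Replicate 1 was highest for the glycine receptor subunit Glrb at 112.2, the neuronal enolase Eno2 at 358, Itm2a at 65.3 and the histone gene Hist2h2aa1 at 21 FPKM. In replicate 1 the level of the monoamine receptor list was lowest at 36.9, against 38.4 elsewhere, and that of the list of RNAs without a poly(A) tail was highest at 77.6, against 72.9 to 73.7. In replicate 4, Ttr, the transthyretin gene of the choroid plexus, was at 49.7 FPKM against 0.587 to 1.99. Outside the annotated genes, 392 loci without an Ensembl identifier were at 1 FPKM or more in all 4 libraries.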

How the results depend on the processing

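The limited prior of the main results, the prior from randomly paired genes and the background of all genes were chosen after seeing the data. The limma prior without a limit on its degrees of freedom, given as an alternative, was the planned one. Of the 31 named gene pairs run under all 10 alternatives, 17 kept their direction and side of the threshold, as did 23 of the 38 lists run under all 8. Vipr1 without replicate 4 and Slc6a4 without replicate 2 fell below the filter, and the pituitary list had too few genes at 1 FPKM or more, so these gave no value there. Without length correction, precursors above Adcyap1 fell to 0, transmitter genes above Slc17a6 to 1, and 5 lists passed as below. It also reversed Cck (-0.94), Sst (-0.68) and Penk (-0.47) against Adcyap1, and Th (-0.38) and Ddc (-0.69) against Slc17a6. Leaving out 1 library, Hcrt ranged from -1.442 to 0.0252, reversed without replicate 3, and Ddc from -0.0143 to 0.486, reversed without replicate 2; neither had passed. The same gave 3 to 6 higher precursors, lowest without replicate 2 or 4, 1 to 2 lists below, with blood cells added without replicate 2, and 0 to 8 genes in the variance test, with 4 without replicate 3 and 8 without replicate 4. The planned limma prior gave 5 transmitter genes above Slc17a6, adding Slc6a3 and Ddc, and 40 precursors below Adcyap1. With a background of 1 FPKM or more, 5 lists passed as above and 2 as below, and with all genes as the background 0 passed as below. Median agreement between libraries was 0.9810 for genes at 1 FPKM or more. At a threshold of 10, 5689 entries were detected, with loci without an Ensembl identifier counted among the entries searched. The causes of the changes under the alternatives were not tested. No paired analysis was possible because the samples form 1 group. Count-based tests, replacement of the length, the prior count, detection by counts and the biological coefficient of variation were not run, because the values were read as FPKM. Depth of 19300000 to 20900000 fragments limits genes near 0.1 FPKM.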

Other observations

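The background of all genes was chosen after the result was seen; the levels are those of lists fixed beforehand, and none of them passed with the settings of the report, though some did under alternatives. Potassium and HCN channel genes stood at 64.9 ± 1.79 (median percentile, SD, n = 4), with the pacemaker channel Hcn2 at 91.7 ± 11.6 FPKM and the glial potassium channel Kcnj10 at 84.3 ± 6.30 FPKM. Sodium and calcium channels stood at 59.7 ± 3.85, ionotropic glutamate receptors at 56.0 ± 3.07 with Grin1 at 69.9 ± 3.29 FPKM, and GABA-A and glycine receptors at 67.0 ± 1.05 with Glrb at 103.6 ± 5.71 FPKM. Monoamine receptors stood at 38.0 ± 0.716, with the serotonin receptor Htr2c at 29.0 ± 2.87 FPKM. Glucocorticoid and stress genes stood at 71.6 ± 2.21, with Mt1 at 281.6 ± 21.6 FPKM, and immediate early genes at 51.2 ± 0.468, with Fos, a marker of recent activity, at 14.4 ± 5.06 FPKM.

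Without length correction, potassium and HCN channels passed as above at 75.2 and sodium and calcium channels at 74.5, and by mean log2 level potassium and HCN channels passed at 3.42 and glucocorticoid and stress genes at 4.16. Monoamine receptors passed as below at 24.3 with a background of 1 FPKM or more. With all genes as the background, potassium and HCN channels passed at 75.3, GABA-A and glycine receptors at 76.3 and glucocorticoid and stress genes at 80.0.

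Neuropeptide precursors as a list stood at 45.4 ± 9.39, glutamatergic genes at 73.7 ± 14.4 and monoaminergic and cholinergic genes at 75.7 ± 8.11. Among cell types, microglia stood at 73.6 ± 0.277, oligodendrocyte precursors at 70.0 ± 2.11, endothelium at 62.1 ± 1.68 with the tight junction gene Cldn5 at 34.9 ± 6.51 FPKM, and mural cells and fibroblasts at 48.1 ± 1.73. Ependyma stood at 40.0 ± 1.41, blood cells at 30.2 ± 15.5, choroid plexus at 27.0 ± 3.63 and pituitary genes at 26.3 ± 15.6. Levels leave out listed genes that did not pass the filter, so only 7 of 11 blood cell genes and 4 of 8 pituitary genes entered. Heat shock genes stood at 71.4 ± 3.76 with Hsp90aa1 at 401 ± 10.2 FPKM. The list of RNAs without a poly(A) tail stood at 74.5 ± 2.13 on 5 of 13 listed genes, and sex-linked genes at 50.03 ± 0.238 on 4 of 6. The former level rests on histone genes such as Hist2h2aa1, while Rmrp, Rn45s, Rn7sk and Rpph1 had no entry. It does not show how well RNA without a tail was captured. Without length correction, neuropeptide precursors passed as below at 23.1 and blood cells at 11.7. Blood cells stood at 16.2 without replicate 2, where they passed as below, and at 16.7 without replicate 4, where they did not. Microglia passed as above by mean log2 level, at 3.95, and with all genes as the background, at 81.4. The haemoglobin gene Hbb-bs was at 18.9 FPKM in replicate 1 and 1.33 FPKM in replicate 2, and the blood list was 2.53 log2 units above the mean of the other libraries in replicate 1 and at -2.44 in replicate 2. The Y-linked gene Ddx3y was alike in the libraries, at 13.6 to 15.4 FPKM.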
